A study of Escherichia coli with 24 samples.

How the data were processed

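RNA-seq was done on Escherichia coli NCM3722, a prototrophic wild type, and on CY104, which the labels describe as lacking crp and cyaA. Per the labels' protocols, cells grew aerobically in shaken batch culture in a minimal salts medium with ammonium and a single carbon source, and RNA was extracted in exponential phase with a phenol-based reagent and a silica column. The carbon sources are given in the labels as Ace, G6P, Glc, Gly, Lac, Sor and Suc, and these names are kept here. There were 24 libraries in 8 groups of 3, 7 groups of the wild type and 1 of CY104 on Glc. Replicate numbers came from the sample titles. No label says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

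Each sample had 1 table of features with a column of raw counts and a column of RPKM, per the file headers. The deposited counts were whole numbers, not normalized, and summed to between 13338428 for G6P library 3 and 19428658 for CY104 library 2. The deposited RPKM values were the authors' counts divided by feature length and by a depth that was 88.0 to 89.5% of the count total. They were not tested, because the counts they derive from were at hand. Reads were aligned with Bowtie2 2.3.2, per the submitters' processing notes. The counting tool, its strand setting and its handling of reads that map to several places are not given in the sources used here. Counts of overlapping and antisense features are therefore uncertain, as are those of near-identical copies such as tufA and tufB, gadA and gadB, and insertion elements. The tables listed 4637 features on 2 replicons, the NCM3722 chromosome and its plasmid, of which 115 were noncoding RNAs and 77 lay on the plasmid. No ribosomal or transfer RNA was among them, so the share of ribosomal RNA is unknown. Coordinates are those of the NCM3722 sequences named in the tables, counted from 1. A column was assigned to the sample whose table it stood in.

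Counts were tested with edgeR 4.0.16 in R 4.3.3. Features with low counts were removed by filterByExpr with the 8 groups, which left 4419. All 24 libraries entered 1 fit with TMM normalization and robust quasi-likelihood dispersions, and each group was compared with wild type on Glc, the source used for both strains. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. CPM values are TMM-normalized and given as mean ± SD of 3 libraries, and log2 fold changes are given with their standard errors. A quasi-likelihood F test asked which genes differed among the 7 sources in the wild type. A gene was called specific to a source when its 6 log2 fold changes against the other sources shared a sign, were all at least 1 in size, and the largest of the 6 p-values passed after adjustment over genes. TMM factors ran from 0.918 to 1.08 in the wild type and from 1.20 to 1.25 in CY104, and the 10 most abundant features took 13.7 to 16.6% of counts. The common biological coefficient of variation was 9.67%.

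Lists of genes were fixed from textbook knowledge: 30 lists with 545 members, of which 542 matched a symbol in the tables, 5 of them under another name. The lists of at least 3 measured members, 29 in all, were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 203 pairs of list and comparison. Camera called 127 pairs. With a correlation estimated from the data it called 60, all among the 127. Members that rose or fell were counted by edgeR's adjusted p over all genes and again adjusted over the list alone. The lists, tests, groups, alternatives and the rule for naming genes were set before the data were examined. That rule allows crp and cyaA, the 10 highest and 10 lowest called genes per comparison with at least a 2-fold change, a mean of at least 20 CPM in the higher group and no overlap between libraries, up to 4 leading members of each list, the leading specific genes, and all members of the substrate operon lists.

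For a gene at 0 counts in all libraries of a group, the fold change is a lower bound computed against a floor of 3 counts over that group's 3 libraries. A count of 0 in a single library allows up to 0.154 to 0.225 CPM at these depths. Intervals and floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules. No pair of libraries of a group was alike within sampling noise: their log2 raw counts correlated at 0.987 to 0.993, and a chi-square statistic per degree of freedom between them was at least 4.53.

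Libraries of different groups share replicate numbers. Deviations from the group means were correlated across genes between same-numbered libraries, and of the 28 pairs of groups only Glc and Lac had every correlation above 0.1, at 0.206, 0.162 and 0.448. Deviations within a group cancel, so these correlations are not separate pieces of evidence. A profile shared by library 3 of Glc and library 3 of Lac also raises the correlations of the other libraries. Both were high in zinc-uptake transcripts, so the correlations cannot decide whether the numbers pair these 2 groups. The pairing was assumed, from the data and not from the labels. Values with a replicate block are given where they change a result.

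On counts simulated for Ace against Glc over 4377 genes, with 50 genes changed at each fold, the pairwise test recovered 78% of genes changed 1.5-fold, 92% at 2-fold, 100% at 4-fold and 98% at 8-fold, with 12 false calls among 4177 unchanged genes. In the same simulation the test of specificity recovered 0% at 1.5-fold, 8% at 2-fold, 98% at 4-fold and 96% at 8-fold, with 0 false calls.

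Alternatives were RLE and upper-quartile normalization, no filter or a mean of at least 50 counts, DESeq2 1.42.0, a fit of only the 6 libraries compared, a replicate block, leaving out each library in turn, other fold thresholds, another reference for the sources, and an estimated correlation for the lists. Others were added after seeing the data: leaving out library 3 of Glc, Lac and G6P, which held high zinc-uptake transcripts, leaving out noncoding RNAs, and leaving out genes absent from 1 strain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some results on single genes are not reported here.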

Results

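Transcripts of Escherichia coli NCM3722 were counted in 24 RNA-seq libraries. The wild type had grown on each of 7 carbon sources, named Ace, G6P, Glc, Gly, Lac, Sor and Suc in the labels, with 3 libraries per source, and strain CY104, which lacks crp and cyaA, had grown on Glc with 3 libraries. Total counts per library ranged from 13338428 to 19428658. The design asks how expression depends on the carbon source and on crp, the gene of the cAMP receptor protein that activates many catabolic operons, together with cyaA, the gene of the adenylate cyclase that makes cAMP. Each group was compared with the wild type on Glc.

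The targeted genes were examined first. crp (AA953_RS00430, chromosome 62459 to 63091, plus strand, a coding gene) had 0, 0 and 2 counts in the 3 CY104 libraries against 8027, 7742 and 7938 in the 3 Glc libraries, a 17762-fold lower level with a 95% counting interval of 4916 to 146675. cyaA (AA953_RS02805, chromosome 568695 to 571241, plus strand, a coding gene) had 0 counts in all 3 CY104 libraries against 7525, 7307 and 7942 on Glc, at least 11375-fold lower. In the 21 wild-type libraries crp counts ran from 5367 to 13667 and cyaA counts from 4071 to 8057. Both genes moved with the source, in opposite directions. crp was at 501 ± 13.9 CPM on Glc and rose to 817 ± 12.1 on Ace, 779.7 ± 24.6 on Suc, 709 ± 5.84 on Sor and 639.6 ± 0.590 on Gly (SD, n = 3; adjusted p = 3.55e-11, 6.14e-10, 3.43e-08 and 2.16e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It fell to 426 ± 15.4 on G6P (adjusted p = 0.00591 by the same test) and was at 484 ± 10.7 on Lac (adjusted p = 0.816). cyaA was at 482 ± 30.0 CPM on Glc and fell to 242.5 ± 12.9 on Sor, 299.5 ± 3.88 on Suc, 329 ± 8.46 on Gly and 360.4 ± 3.79 on Ace (edgeR, adjusted p = 1.68e-15, 9.61e-12, 9.50e-10 and 8.61e-08, n = 3). On G6P and Lac it was at 515 ± 20.6 and 497.5 ± 26.1 CPM and passed no test (adjusted p = 0.196 and 0.797 by edgeR).

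**Figure D1:**
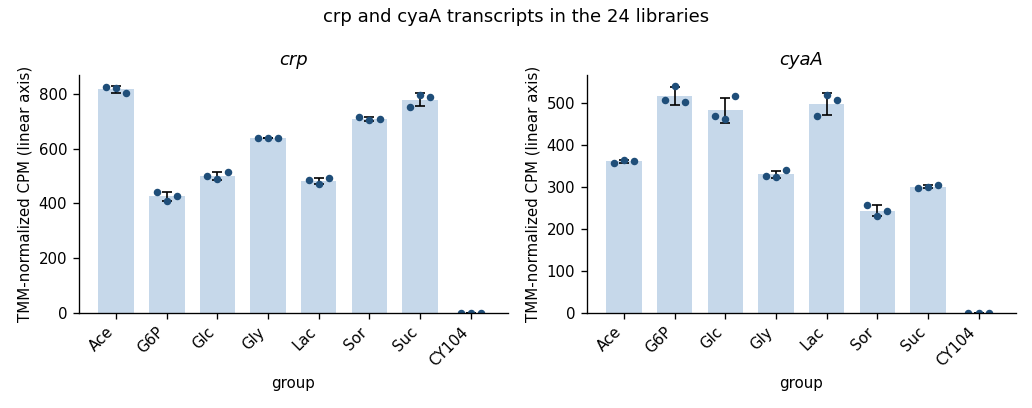
Normalized expression of crp and cyaA in 8 groups, in CPM on a linear axis, with bars for the mean, error bars for the SD and points for the 3 libraries. Both genes are near 0 in CY104, and across the wild type crp is highest on Ace at 817 CPM, where cyaA is at 360.4 CPM.

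Most genes tested differed between the carbon source groups, counting changes of any size. If the libraries of a group came from a single culture, the source cannot be told apart from the culture. Among the 7 sources, 3623 of 4419 genes tested (82.0%) differed in the wild type by edgeR's quasi-likelihood F test. Against Glc, 2918 genes were called on Sor, 2805 on Ace, 2345 on Gly, 2325 on Suc, 1109 on G6P and 92 on Lac, and 2832 were called in CY104 on Glc. Large changes were mostly increases on Sor (773 of 938 genes changed at least 2-fold), Ace (639 of 823), Gly (499 of 592) and Suc (425 of 570). On G6P they were mostly decreases, with 110 of 133 lower, and in CY104 they went both ways, with 498 higher and 386 lower. On Lac 13 genes were at least 2-fold higher and 3 lower. The replicate number was also used as a block in the 6 Glc and Lac libraries alone, a pairing that was assumed. In that fit 140 genes were called between Lac and Glc, 61 higher and 79 lower, of which 70 were among the 92.

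**Figure D2:**
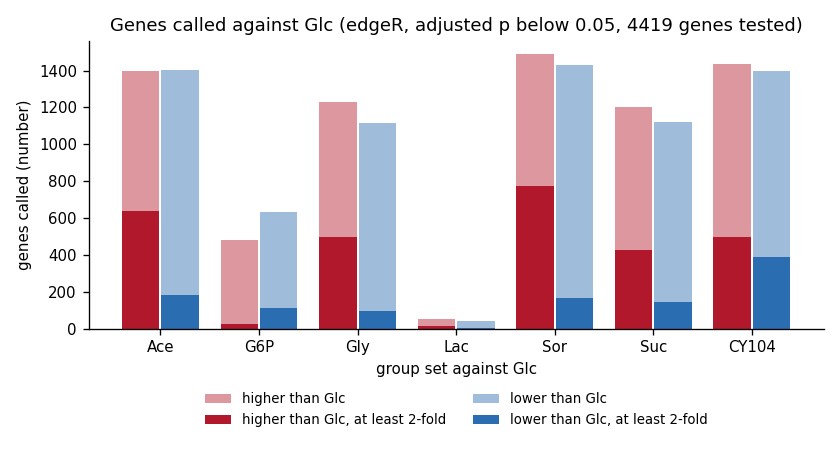
Number of genes called against wild type on Glc in 7 comparisons, with higher and lower as paired bars, light for all calls and dark for changes of at least 2-fold. Sor has the most calls, 2918, and Lac the fewest, 92.

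Library 3 of Glc and library 3 of Lac stood apart in genes of zinc starvation. zinT, a periplasmic zinc-binding protein, was at 4974 and 6832 CPM in them and at 49.4 in G6P library 3, against 2.67 to 16.6 CPM in the other 21 libraries. znuA, the binding protein of the high-affinity zinc importer, was at 4396, 4556 and 407 CPM in the same libraries. Because Glc is the reference, zinT was called lower on Ace, Gly, Sor, Suc and in CY104, with log2 fold changes of -8.44, -7.98, -7.85, -7.79 and -8.98. Without Glc library 3 these were -1.18, -0.72, -0.59, -0.53 and -1.72, and no call held (edgeR, adjusted p = 0.669, 0.806, 0.822, 0.859 and 0.514). Lac library 3, also high in zinT, stayed in this fit and in its estimate of spread. znuA on Ace went from -4.44 to -0.92 and the zinc-independent ribosomal paralogs ykgM and ykgO from -7.80 and -7.58 to -1.497 and -1.25, all likewise without a call. Leaving out library 3 of Glc, Lac and G6P together, called the 3 zinc libraries here and chosen after seeing the data, changed the counts of called genes to 2921 on Sor, 2766 on Ace, 2325 on Gly, 2246 on Suc, 933 on G6P, 106 on Lac and 2802 in CY104. On Ace 2640 of the 2805 earlier calls were kept, on Sor 2780 of 2918 and in CY104 2660 of 2832. Gly kept 2166 of 2345, Suc 2122 of 2325, G6P 821 of 1109 and Lac 62 of 92. In this fit zinT stayed called lower on Ace, Gly, Sor, Suc and in CY104, as did znuA, ykgM and ykgO on Ace. ykgM lost its call on Gly and Suc, and ykgO in CY104.

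**Figure D3:**
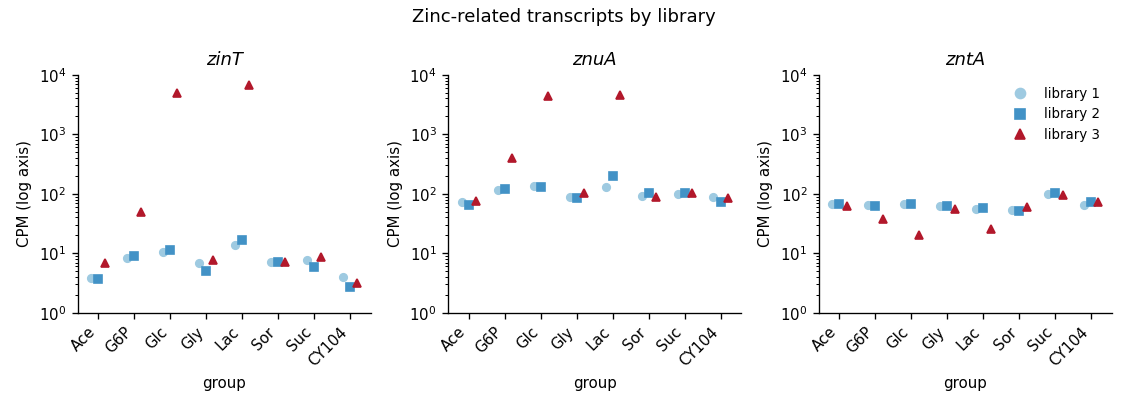
CPM of zinT, znuA and zntA on a log axis in each of the 3 libraries of 8 groups, 1 point per library. zinT reaches 4974 CPM in Glc library 3 and 6832 CPM in Lac library 3, and zntA, a zinc exporter, is at 20.4 and 26.1 CPM in them.

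On Ace hyi, hydroxypyruvate isomerase, rose to 591 ± 30.7 CPM from 0.953 ± 0.237 on Glc (log2 fold change 9.27 ± 0.28, SE; adjusted p = 9.03e-16 by edgeR, n = 3). glxR, tartronate semialdehyde reductase, and gcl, glyoxylate carboligase, rose to 1055 ± 37.2 and 1509 ± 109 CPM (log2 9.23 ± 0.16 and 8.41 ± 0.18), and the propionate gene prpB rose to 304 ± 23.2 CPM from 0.550 ± 0.313. aceA, isocitrate lyase, rose from 129 ± 3.47 to 11603 ± 622 CPM (log2 6.50 ± 0.07; edgeR, adjusted p = 2.50e-34) and aceB, malate synthase, from 105 ± 2.81 to 6512 ± 179 CPM. The gluconeogenic pck, PEP carboxykinase, rose to 3427 ± 156 CPM from 286 ± 18.8. ptsG, the glucose transporter of the phosphotransferase system, fell from 1622 ± 124 to 279 ± 8.43 CPM (log2 -2.54 ± 0.05; edgeR, adjusted p = 2.36e-26), and the glycolytic gpmM, phosphoglycerate mutase, from 551 ± 3.07 to 102 ± 2.29 CPM.

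By list, all 7 genes of acetate uptake and the glyoxylate shunt rose on Ace (median log2 4.99; camera, adjusted p = 5.27e-09), all 8 of fatty acid degradation (2.25; adjusted p = 1.04e-07), all 5 of gluconeogenesis and malic enzymes (1.78; adjusted p = 3.86e-05) and 8 of 9 of glycerol use (1.35; adjusted p = 0.000196). Of 57 genes for other sugars, 47 rose and 2 fell (1.53; camera, adjusted p = 1.07e-12), led by lamB, the maltoporin, at log2 4.18, and of 29 for amino acid and nucleoside catabolism 24 rose and 4 fell (1.56; adjusted p = 3.16e-08), led by tnaA, tryptophanase, at 3.62. Of 15 genes of the tricarboxylic acid cycle 14 rose, among them fumA and sucC at log2 1.86 and 1.80 (camera, adjusted p = 8.93e-09, and adjusted p = 0.101 with an estimated correlation). All 7 members of the glucose phosphotransferase system fell (median -0.86; camera, adjusted p = 3.19e-05), and of 12 glycolytic genes 10 fell and 2 rose (median -0.57; adjusted p = 0.000283). The 3 lactose genes also rose, to CPM of 18.4 ± 1.08 for lacZ (log2 0.82), though the list was not called (camera, adjusted p = 0.148). Genes specific to Ace, at least 2-fold apart from every other source, numbered 43 higher and 9 lower. glxR, hyi, gcl and allB, allantoinase, led them, and thrA, aspartokinase, led the lower ones at 789 ± 10.8 CPM.

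On G6P uhpT, the hexose phosphate transporter, rose to 2984 ± 110.3 CPM from 4.06 ± 1.501 on Glc, a log2 fold change of 9.52 ± 0.21 (edgeR, adjusted p = 1.87e-16, n = 3). On the other sources it stayed between 3.18 and 14.2 CPM. btsT, a pyruvate transporter, rose to 72.6 ± 4.43 CPM from 6.15 ± 0.540, and ompC, an osmoregulated porin, to 9481 ± 1614 from 2857 ± 879 (log2 3.56 ± 0.11 and 1.73 ± 0.18). ptsG fell from 1622 ± 124 to 139 ± 3.61 CPM (log2 -3.55 ± 0.06; edgeR, adjusted p = 7.14e-29) and manX, of the mannose transporter, from 643 ± 83.6 to 59.4 ± 6.32 CPM. malT, the activator of the maltose genes, fell from 676 ± 78.0 to 88.3 ± 2.37 CPM. ppsA, PEP synthetase, fell from 1149.9 ± 40.2 to 438 ± 10.8 CPM, and acs, acetyl-CoA synthetase, from 266 ± 27.0 to 69.3 ± 5.39 CPM.

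All 7 genes of the phosphotransferase list fell on G6P (median log2 -3.14; camera, adjusted p = 7.75e-22). Of 12 glycolytic genes 10 rose and 2 fell, led by pykF, pyruvate kinase, at log2 0.84 and eno, enolase, at 0.78 (median 0.49; camera, adjusted p = 9.14e-11). Genes for other sugars fell in 29 of 57 cases, or 33 adjusted over the list alone, and none rose (median -0.38; camera, adjusted p = 6.43e-12). Those of acetate uptake and the glyoxylate shunt fell in 6 of 7, fatty acid degradation in 7 of 8 with 1 rising, and gluconeogenesis in 5 of 5 (camera, adjusted p = 5.62e-09, 1.43e-09 and 5.15e-05). Amino acid and nucleoside catabolism fell in 16 of 29 with 1 rising, or 17 and 2 adjusted over the list alone (camera, adjusted p = 3.27e-06). In the tricarboxylic acid cycle 13 of 15 fell, among them mdh and gltA at log2 -0.71 and -0.65 (camera, adjusted p = 2.65e-08, and adjusted p = 0.112 with an estimated correlation). Of the 4 glucose 6-phosphate uptake genes only uhpT rose, or 2 rose and 1 fell adjusted over the list alone, and the list was not called (camera, adjusted p = 0.0530). The 10 genes specific to G6P and higher were led by uhpT, btsT and tsgA, and 54 were specific and lower, led by malE, the maltose-binding protein, at 6.06 ± 3.90 CPM.

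On Gly the glycerol regulon stood out. glpF, the glycerol channel, rose to 2846 ± 91.1 CPM from 4.79 ± 0.756 on Glc (log2 9.21 ± 0.20; edgeR, adjusted p = 2.56e-17, n = 3). glpK, glycerol kinase, rose to 7528 ± 78.6 from 26.1 ± 4.67, and glpD, aerobic glycerol 3-phosphate dehydrogenase, to 3506 ± 45.2 from 15.7 ± 0.710 (log2 8.17 ± 0.10 and 7.80 ± 0.08). glpX, a fructose bisphosphatase cotranscribed with glpFK, rose to 376 ± 13.2 CPM and lay between 54.8 and 61.4 on the other sources. Flagellar genes rose with them, fliA, the flagellar sigma factor, to 119 ± 10.1 from 2.67 ± 1.22 CPM. ompC fell to 477 ± 8.92 CPM, ptsG to 299 ± 6.36 and mqo, malate:quinone oxidoreductase, to 30.1 ± 4.38 from 155.0 ± 12.4 (edgeR, adjusted p = 2.06e-09, 1.79e-25 and 4.04e-19).

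All 9 glycerol genes rose on Gly (median log2 7.80; camera, adjusted p = 1.46e-14), as did all 7 of acetate uptake and the glyoxylate shunt, led by actP, an acetate permease, at 4.29 (2.31; adjusted p = 7.82e-09), and all 8 of fatty acid degradation (1.96; adjusted p = 1.45e-09). Other sugars rose in 48 of 57 with none falling, and amino acid and nucleoside catabolism in 22 of 29 with 5 falling (camera, adjusted p = 1.72e-16 and 9.37e-07). The phosphotransferase genes fell in 7 of 7 (median -0.72; camera, adjusted p = 8.43e-08) and glycolytic genes in 8 of 12 with 2 rising, or 9 adjusted over the list alone (-0.31; adjusted p = 0.000579). Of the 15 cycle genes 11 rose (median 0.39; camera, adjusted p = 0.000459, and adjusted p = 0.284 with an estimated correlation). Gluconeogenesis rose in 4 of 5 with 1 falling (1.03; camera, adjusted p = 0.00330, and adjusted p = 0.0826 with an estimated correlation). Specific to Gly were 12 genes, all higher, 9 of them in the glycerol list and the others dhaK, dhaL and dhaM of dihydroxyacetone kinase, with dhaL at 229.6 ± 18.2 CPM.

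On Lac lacZ, beta-galactosidase, rose to 5084 ± 423 CPM from 10.4 ± 1.53 (log2 8.93 ± 0.16; edgeR, adjusted p = 4.22e-19, n = 3), lacY, lactose permease, to 763 ± 117 from 2.66 ± 0.320 and lacA to 442 ± 58.0 from 2.86 ± 0.587. galK, galactokinase, and galT, a uridylyltransferase, rose by log2 3.75 ± 0.08 and 3.72 ± 0.07, galT to 1167 ± 85.0 CPM. melA, alpha-galactosidase, and galP, galactose permease, rose by 2.21 and 2.11. Of 12 glycolytic genes 8 rose, or 9 adjusted over the list alone, led by pykF at log2 0.49 ± 0.05 and eno at 0.43 ± 0.04 (median 0.26; camera, adjusted p = 9.17e-16). ppsA fell from 1149.9 ± 40.2 to 720.0 ± 80.2 CPM (log2 -0.68 ± 0.06; edgeR, adjusted p = 9.35e-10). No lower gene met the rule for naming the most changed genes.

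Several lists shifted on Lac with few members passing on their own. Other sugars had 8 of 57 higher, or 12 higher and 1 lower adjusted over the list alone, and a median of 0.02 (camera, adjusted p = 5.79e-09). Amino acid and nucleoside catabolism had 6 of 29 lower, among them nupG, a nucleoside transporter, at log2 -0.49, or 14 adjusted over the list alone, and 2 without the 3 zinc libraries (median -0.22; camera, adjusted p = 1.88e-10). Gluconeogenesis had 1 of 5 lower, or 3 adjusted over the list alone (camera, adjusted p = 0.000598). Acetate uptake and the glyoxylate shunt had aceB lower at log2 -0.31, or 3 of 7 adjusted over the list alone (camera, adjusted p = 0.000191, and adjusted p = 0.124 with an estimated correlation). The phosphotransferase list had 2 of 7 lower, or 4 adjusted over the list alone (median -0.21; camera, adjusted p = 0.0450, and adjusted p = 0.262 with an estimated correlation). Fatty acid degradation had 1 of 8 lower, or 1 higher and 5 lower adjusted over the list alone (median -0.19; camera, adjusted p = 0.00332, and adjusted p = 0.219 with an estimated correlation). With a replicate block in the fit of the 6 Glc and Lac libraries, 13 of the other sugars rose, and 2 fatty acid, 2 gluconeogenesis and 3 phosphotransferase genes fell. No camera call changed, with p-values in that fit adjusted over the 29 lists on Lac and not over the 203 pairs. Translation factors and aminoacyl-tRNA synthetases stayed called in it only narrowly (camera, adjusted p = 0.0492). General stress then had 5 genes falling in place of 4, and amino acid biosynthesis 2 rising in place of 1. Pentose phosphate and Entner-Doudoroff genes went from 1 rising and 1 falling to 0 of each. In the cycle and in glycerol use 0 members were called by edgeR (camera, adjusted p = 0.553 and 0.158). Genes specific to Lac, all higher, included lacZ, lacY, lacA, galT and galK.

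On Sor the 4 highest of the genes that met the naming rule were srlA, srlE, srlB and srlD of the sorbitol operon. srlA and srlE, of the glucitol phosphotransferase transporter, reached 1658 ± 106 and 2852 ± 208 CPM from 2.20 ± 0.118 and 5.29 ± 1.33 on Glc (log2 9.55 ± 0.35 and 9.07 ± 0.30; edgeR, adjusted p = 7.39e-14 and 1.16e-14, n = 3). srlD, sorbitol 6-phosphate dehydrogenase, reached 3729.6 ± 237 CPM. lamB rose to 3113 ± 90.1 CPM from 13.8 ± 7.00 and malE to 3569 ± 121 from 46.0 ± 15.8 (log2 7.81 ± 0.45 and 6.28 ± 0.35). modA, the molybdate-binding protein, was specific to Sor with a smallest log2 fold change of 3.92 against any other source. mqo fell to 20.5 ± 0.835 CPM (log2 -2.92 ± 0.09; edgeR, adjusted p = 2.40e-21) and rhlE, an RNA helicase, to 16.2 ± 0.372 from 89.8 ± 9.74 CPM.

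All 6 sorbitol genes rose on Sor (median log2 8.08; camera, adjusted p = 3.31e-06), all 7 of acetate uptake and the glyoxylate shunt (2.94; adjusted p = 4.34e-07), all 8 of fatty acid degradation (2.67; adjusted p = 1.22e-07) and 8 of 9 of glycerol use (1.52; adjusted p = 0.000566). Other sugars rose in 48 of 57 with 1 falling, and amino acid and nucleoside catabolism in 24 of 29 with 3 falling, tnaA by log2 4.66 (camera, adjusted p = 2.37e-16 and 3.71e-07). Glycolytic genes fell in 10 of 12 with 2 rising, pykF by -1.63 and gapA, glyceraldehyde 3-phosphate dehydrogenase, by -1.13 (median -0.66; camera, adjusted p = 3.19e-05). Phosphotransferase genes fell in 4 of 7, with ptsG at 578 ± 21.9 CPM (median -0.57; camera, adjusted p = 0.0129, and adjusted p = 0.181 with an estimated correlation). In gluconeogenesis 4 of 5 rose and fbp, fructose bisphosphatase, fell by 0.38 on the log2 scale (camera, adjusted p = 0.0342, and adjusted p = 0.199 with an estimated correlation). Cycle genes rose in 8 of 15 with 1 falling, or 3 falling without the 3 zinc libraries, and the list was not called (camera, adjusted p = 0.0692). Genes specific to Sor numbered 38, all higher, led by srlE, srlA, srlB and srlD.

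On Suc tar, the aspartate chemoreceptor, rose to 135 ± 23.8 CPM from 4.28 ± 0.779 on Glc (log2 4.97 ± 0.15; edgeR, adjusted p = 1.29e-20, n = 3) and fliC, flagellin, to 1603 ± 218 from 52.4 ± 20.9 (4.93 ± 0.24). dctA, the aerobic C4-dicarboxylate transporter, rose to 2216 ± 179.6 from 119.7 ± 22.5 CPM (4.21 ± 0.12; edgeR, adjusted p = 6.83e-18) and dcuB, an anaerobic one, to 36.7 ± 4.05 from 3.74 ± 0.198. pck rose to 2822 ± 89.9 CPM and ppsA to 4707 ± 192. ompC fell to 478 ± 25.2 CPM, ptsG to 273 ± 7.55 and edd, of the Entner-Doudoroff pathway, to 9.52 ± 0.565 from 35.1 ± 2.85 (edgeR, adjusted p = 2.09e-09, 1.44e-25 and 1.86e-15).

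Of the 15 cycle genes all rose on Suc, fumA by log2 1.74 and sucC by 1.39 (median 0.92; camera, adjusted p = 2.37e-10, and adjusted p = 0.0669 with an estimated correlation). All 7 of acetate uptake and the glyoxylate shunt rose (2.13; camera, adjusted p = 4.54e-09), all 8 of fatty acid degradation (1.91; adjusted p = 1.07e-09), all 5 of gluconeogenesis (1.74; adjusted p = 9.98e-07) and 5 of 9 of glycerol use (0.66; adjusted p = 0.00430). Other sugars rose in 48 of 57 with 2 falling and amino acid and nucleoside catabolism in 24 of 29 with 2 falling (camera, adjusted p = 2.37e-16 and 1.47e-09). All 7 phosphotransferase genes fell (median -0.93; camera, adjusted p = 9.83e-09), as did 9 of 12 glycolytic genes with 1 rising, gpmM by -1.77 (-0.47; adjusted p = 1.20e-05). The sorbitol list had 5 of 6 higher at low levels, srlE at 18.8 ± 0.545 CPM (camera, adjusted p = 0.0129, and adjusted p = 0.239 with an estimated correlation). Only 3 genes were specific to Suc, all higher: dcuB, dctA and fumB, an anaerobic fumarase, at 48.7 ± 8.96 CPM.

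CY104 on Glc changed about as many genes as the wild type did on Ace. The strains also differed in blocks of neighbouring genes at 0 counts in 1 of them, described below. The comparison therefore cannot assign a change to the loss of crp and cyaA alone. wzc, a tyrosine kinase of capsule export, rose to 337 ± 19.9 CPM from 0.760 ± 0.162 (log2 8.78 ± 0.21; edgeR, adjusted p = 6.88e-22, n = 3) and hdeB, a periplasmic acid chaperone, to 550.0 ± 42.6 from 8.54 ± 0.411 (6.01 ± 0.11). tktB, transketolase 2, rose to 1250.3 ± 126 CPM from 132 ± 12.5. nmpC, an outer membrane porin, fell from 11869 ± 954 to 46.7 ± 5.37 CPM (log2 -7.99 ± 0.09; edgeR, adjusted p = 5.09e-33) and aldA, aldehyde dehydrogenase, from 843 ± 89.8 to 11.4 ± 1.53. sdhA, of succinate dehydrogenase, fell from 2142 ± 147 to 264 ± 5.37 CPM, dctA to 8.37 ± 0.691, ptsG to 181 ± 4.63 and manX to 65.9 ± 3.36. yhfK, which lies beside crp at 63142 to 65232, fell to 1.71 ± 0.478 from 79.6 ± 6.91 CPM. Some genes were at 0 counts in the 3 libraries of 1 strain on Glc: ravA, trkD, rbsB and rbsK in the wild type, at least 1221, 833.5, 605.5 and 419-fold higher in CY104, and intZ and yffS in CY104, at least 847 and 845-fold lower.

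Of the 15 cycle genes 12 fell in CY104 and 1 rose (median log2 -1.91; camera, adjusted p = 9.69e-07, and adjusted p = 0.155 with an estimated correlation). The phosphotransferase list fell in 6 of 7, or 7 adjusted over the list alone (median -2.97; camera, adjusted p = 2.96e-06). Fatty acid degradation fell in 7 of 8 with 1 rising, fadL by -1.18 (camera, adjusted p = 0.0118, and adjusted p = 0.271 with an estimated correlation), and the sorbitol operon in 4 of 6, srlD to 4.53 ± 0.421 CPM (adjusted p = 0.0217, and adjusted p = 0.262 with an estimated correlation). Acetate genes split, with aceB and aceA higher by 2.19 and 1.88 and acs and actP lower by log2 fold changes of -2.06 and -2.09 (4 rose and 3 fell; camera, adjusted p = 0.439). Other sugars split too, 19 higher and 25 lower, with a median of -0.15 and a mean of 0.40 (camera, adjusted p = 0.408). Without the rbs genes, left out after seeing that they had 0 counts in the wild type, 14 of 52 rose and 25 fell (median -0.35), and with them at their bounds the median was -0.15. Amino acid and nucleoside catabolism had 13 higher and 10 lower of 29, with a median of 0.10 and a mean of -0.12 (camera, adjusted p = 0.930), among them cstA, a pyruvate transporter, lower at 42.1 ± 2.12 CPM. Gluconeogenesis had 2 higher and 3 lower, ppsA at 1.38 and pck at -2.16 (camera, adjusted p = 0.713), glycolysis 3 higher and 6 lower of 12 (adjusted p = 0.273), and glycerol use 3 higher and 2 lower (adjusted p = 0.602). lacZ fell to 3.66 ± 0.797 CPM and lacA rose to 4.495 ± 0.453 (camera on the 3 lactose genes, adjusted p = 0.702).

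**Figure D4:**
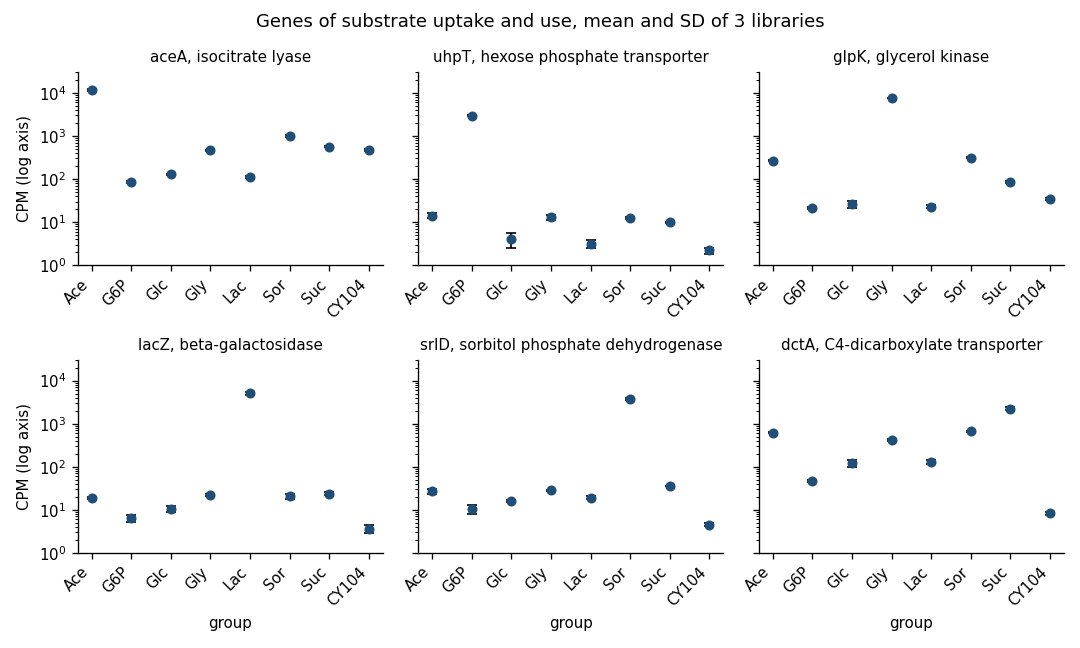
Mean CPM on a log axis with SD of 3 libraries for aceA, uhpT, glpK, lacZ, srlD and dctA in 8 groups, 1 panel per gene. Each is highest on 1 source, with uhpT at 2984 CPM on G6P, glpK at 7528 on Gly and lacZ at 5084 on Lac.

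Specificity was tested for each of the 7 sources against the other 6. By edgeR, 52 genes were specific to Ace, 64 to G6P, 12 to Gly, 8 to Lac, 38 to Sor and 3 to Suc. None was specific to Glc, where an unadjusted p below 0.05 gave 0 higher and 1 lower gene. DESeq2 was not run for this test. Genes of the substrate lists were also counted on other sources. acs was at 3451 CPM on Sor against 3589 on Ace, and actP was higher on Sor than on Ace, at 1955 against 1304 CPM. lacZ reached 22.2 ± 1.28 CPM on Gly and 23.8 ± 2.09 on Suc, and glpK reached 315.6 ± 14.0 on Sor, where it rose by log2 3.60. dctA was at 621.6 ± 10.2 CPM on Ace and 658.3 ± 31.7 on Sor. The C4-dicarboxylate list was called nowhere (camera, adjusted p = 0.112 on Suc, where 3 of 5 rose and 1 fell, and 0.166 in CY104). Lactate use rose in all 4 genes on Ace, Gly, Sor and Suc, lldP, lactate permease, by log2 2.64 on Ace and 1.54 on Gly (camera, adjusted p = 0.000699, 0.00144, 0.00466 and 0.000185). With an estimated correlation the adjusted p was 0.0785, 0.101, 0.136 and 0.0493. On G6P 2 lactate genes fell and in CY104 3 rose (camera, adjusted p = 0.0491 and 0.137, and for G6P adjusted p = 0.273 with an estimated correlation), and on Lac 0 were called by edgeR (camera, adjusted p = 0.317). The lactose list had 3 of 3 higher on Gly, Sor and Suc and 1 lower on G6P without a camera call (adjusted p = 0.0744, 0.0983, 0.0660 and 0.178). The sorbitol list had 5 of 6 higher on Ace, or 6 adjusted over the list alone, 4 higher on Gly and 2 lower on G6P, again without a call (camera, adjusted p = 0.0804, 0.0619 and 0.0509). On G6P 4 of 9 glycerol genes fell, or 1 without the 3 zinc libraries (camera, adjusted p = 0.154).

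Genes of the translation machinery fell on Ace, Gly, Sor and Suc and in CY104. All 54 ribosomal protein genes fell on Ace, Gly, Sor and in CY104, with median log2 fold changes of -0.67, -0.35, -0.78 and -1.12, and 37 fell on Suc, or 40 adjusted over the list alone (median -0.19). Camera gave adjusted p = 5.03e-19, 5.08e-16, 2.72e-21, 1.81e-24 and 4.54e-09 for these 5, and with an estimated correlation Suc was lost (adjusted p = 0.135). rplY fell from 1023 ± 17.5 to 352 ± 15.4 CPM in CY104 (edgeR, adjusted p = 1.55e-19, n = 3) and rpsR to 797 ± 24.7 from 2054 ± 117. On G6P 20 rose, or 23 adjusted over the list alone and 12 without the 3 zinc libraries, rpsQ by 0.25 (median 0.12; camera, adjusted p = 3.84e-07, and adjusted p = 0.196 with an estimated correlation). On Lac 0 were called by edgeR (median 0.06; camera, adjusted p = 1.05e-05, and adjusted p = 0.253 with an estimated correlation). Of 34 translation factors and aminoacyl-tRNA synthetases, all fell on Ace and Sor, 28 on Gly, or 31 adjusted over the list alone, 17 on Suc and 30 in CY104, where tsf, elongation factor Ts, fell by log2 -0.92. Camera called each (adjusted p = 1.29e-11, 4.57e-12, 2.43e-08, 0.00138 and 5.75e-08), and with an estimated correlation Gly, Suc and CY104 were lost (adjusted p = 0.111, 0.327 and 0.118). On G6P 9 rose, or 10 adjusted over the list alone, and on Lac 0 (camera, adjusted p = 0.000369 and 0.0106, and adjusted p = 0.278 and 0.428 with an estimated correlation).

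Flagellar and chemotaxis genes divided the sources. All 51 rose on Gly, Sor and Suc, with median log2 fold changes of 3.98, 3.09 and 3.60 (camera, adjusted p = 6.82e-31, 1.72e-16 and 4.98e-29). On Gly flgB, a rod protein, rose to 83.7 ± 1.76 from 1.83 ± 1.71 CPM (edgeR, adjusted p = 9.31e-11, n = 3), and on Sor to 52.4 ± 4.05. On Ace 6 rose and 0 fell, or 2 rose adjusted over the list alone, with a median of 0.06 that became -0.01 with upper-quartile scaling (camera, adjusted p = 0.710). Without the 3 zinc libraries, 2 rose and 6 fell on Ace. On G6P 16 fell, or 17 adjusted over the list alone, tar by -1.35, and on Lac 1 rose, or 0 either without those libraries or with a replicate block in the fit of the 6 Glc and Lac libraries (camera, adjusted p = 5.88e-06 and 7.89e-06, and adjusted p = 0.251 and 0.255 with an estimated correlation). In CY104 6 rose and 12 fell, or 5 and 10 adjusted over the list alone, and 4 and 19 without the same libraries (camera, adjusted p = 0.432). There the master regulators flhD and flhC fell to 3.84 ± 0.456 and 3.61 ± 0.381 CPM from 112 ± 6.93 and 119 ± 9.18.

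**Figure D5:**
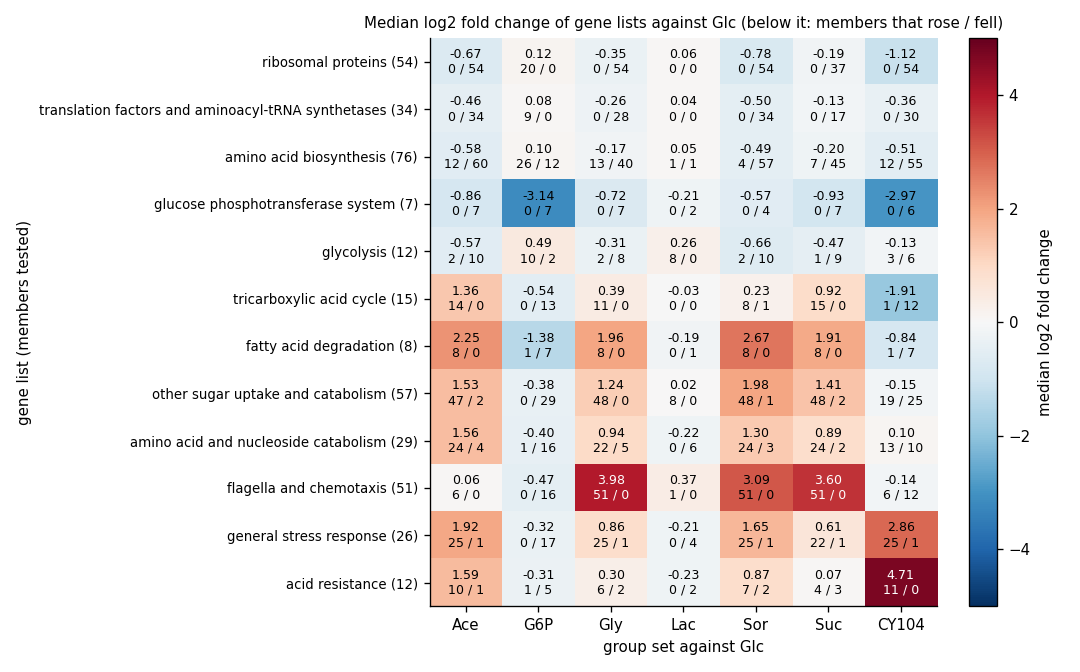
Median log2 fold change against wild type on Glc of 12 gene lists in 7 comparisons, as colours and numbers, with the members that rose and fell written below. Flagella and chemotaxis are at 3.98 on Gly and near 0 on Ace, where the sign turns with upper-quartile scaling, as it does for acid resistance on Suc.

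Amino acid biosynthesis genes mostly fell on Ace, Gly, Sor and Suc and in CY104. Of 76 amino acid biosynthesis genes, 60 fell and 12 rose on Ace, or 13 rose adjusted over the list alone, 40 and 13 on Gly, 57 and 4 on Sor, 45 and 7 on Suc, or 47 fell adjusted over the list alone, and 55 and 12 in CY104, or 13 rose adjusted over the list alone. Camera called all 5 (adjusted p = 1.11e-10, 1.03e-05, 2.14e-11, 8.52e-07 and 2.58e-08), and none held with an estimated correlation (adjusted p = 0.142, 0.294, 0.133, 0.257 and 0.208). The acetolactate synthase genes ilvB and ilvN went the other way on Ace, ilvB to 3217 ± 40.5 from 642 ± 23.0 CPM (edgeR, adjusted p = 2.46e-23, n = 3). In CY104 ilvE, the branched-chain transaminase, fell to 173 ± 9.39 from 1446 ± 46.2 and ilvD to 217 ± 14.4 from 1611 ± 81.0 CPM. On G6P 26 rose and 12 fell, or 34 and 18 adjusted over the list alone, and 25 and 6 without the 3 zinc libraries (camera, adjusted p = 0.00282, and adjusted p = 0.48 with an estimated correlation). On Lac 1 rose and 1 fell (camera, adjusted p = 0.00846, and adjusted p = 0.54 with an estimated correlation). Of 20 genes of nitrogen limitation, 10 rose on each of Ace, Gly, Sor and Suc, led by ddpA, a dipeptide transporter gene, at log2 3.29 on Sor, and 7, 6, 7 and 6 fell, with 7 falling on Gly adjusted over the list alone. Camera called Gly and Suc (adjusted p = 0.0190 and 0.00643, and adjusted p = 0.198 and 0.136 with an estimated correlation) and not Ace or Sor (adjusted p = 0.172 and 0.0613). In CY104 10 fell and 3 rose, glnA, glutamine synthetase, to 379 ± 41.4 from 2214 ± 207 CPM (camera, adjusted p = 0.00366, and adjusted p = 0.118 with an estimated correlation). On G6P 6 rose and 8 fell (adjusted p = 0.145), and on Lac 0 passed, or 1 rose adjusted over the list alone and 2 with a replicate block (camera, adjusted p = 0.00860, and adjusted p = 0.151 with an estimated correlation).

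General stress genes rose on Ace, Gly, Sor and Suc and in CY104. Of 26, 25 rose and 1 fell on Ace, Gly, Sor and in CY104 and 22 rose and 1 fell on Suc, with median log2 fold changes of 1.92, 0.86, 1.65, 2.86 and 0.61. Camera gave adjusted p = 5.86e-13, 6.06e-10, 6.67e-11, 1.45e-16 and 3.16e-06, the last lost with an estimated correlation (adjusted p = 0.135). katE, a catalase, rose to 1982 ± 197 CPM in CY104 from 114 ± 9.81 (edgeR, adjusted p = 4.29e-28, n = 3), dps, a DNA-protecting ferritin, to 721 ± 34.4 on Ace from 87.7 ± 6.47, and csiD, a glutarate hydroxylase, to 225 ± 8.37 on Sor from 18.0 ± 1.49. osmY fell on Suc to 58.1 ± 2.50 from 145 ± 14.8 CPM. On G6P 17 fell, or 18 adjusted over the list alone (camera, adjusted p = 3.84e-07, and adjusted p = 0.107 with an estimated correlation), and on Lac 4 fell, or 10 adjusted over the list alone (median -0.21; camera, adjusted p = 8.26e-10). Of 12 acid resistance genes 11 rose in CY104 (median 4.71; camera, adjusted p = 2.26e-08), where gadE, their activator, went from 0.861 ± 0.404 to 53.4 ± 11.4 CPM. gadA and gadB, near-identical copies with uncertain counts, rose there by 5.97 and 5.82. On Ace 10 rose and 1 fell (median 1.59; camera, adjusted p = 0.00152, and adjusted p = 0.0773 with an estimated correlation), and on Lac 2 fell, or 6 adjusted over the list alone or 0 with a replicate block (median -0.23; adjusted p = 5.52e-05). The list was not called on Gly, Sor, Suc or G6P (camera, adjusted p = 0.663, 0.292, 0.930 and 0.140), where 6, 7, 4 and 1 rose and 2, 2, 3 and 5 fell. Its median on Suc was 0.07 with a downward test and turned sign with upper-quartile scaling. Of 14 heat shock genes 13 fell on Sor and 11 fell and 2 rose in CY104, groES, the chaperonin subunit, to 479.5 ± 23.3 from 805 ± 121 CPM (camera, adjusted p = 0.00349 and 0.00473, and adjusted p = 0.40 and 0.415 with an estimated correlation). On Gly 6 fell, or 3 without the 3 zinc libraries (adjusted p = 0.0428, and adjusted p = 0.558 with an estimated correlation). On Ace 3 rose and 5 fell, on Suc 2 and 4, and without those libraries 5 and 4 on Ace and 5 and 1 on Suc (camera, adjusted p = 0.602 and 0.789). The Suc median was 0.02 against a mean of -0.07, and turned sign with upper-quartile scaling. On G6P and Lac 0 were called by edgeR (camera, adjusted p = 0.469 and 0.376).

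NADH dehydrogenase genes rose on Ace, Gly, Sor and Suc and fell in CY104. All 13 genes of NADH dehydrogenase I rose on Ace, Gly and Suc and 11 on Sor, or 13 adjusted over the list alone and 7 without the 3 zinc libraries, nuoL by log2 0.88 on Ace. In CY104 11 fell, nuoA to 225 ± 9.55 from 377 ± 36.7 CPM (edgeR, adjusted p = 1.88e-11, n = 3). Camera called these 5 (adjusted p = 0.000283, 0.000438, 5.71e-05, 0.0416 and 0.0121), but none with an estimated correlation (adjusted p = 0.376, 0.391, 0.325, 0.624 and 0.540). On G6P 1 fell and on Lac 0 were called (camera, adjusted p = 0.629 and 0.427). All 8 ATP synthase genes rose on Gly and Suc and fell on G6P and in CY104, where atpB fell to 612 ± 22.2 from 1526 ± 67.9 CPM (median 0.40, 0.53, -0.37 and -1.05). Camera called all 4 (adjusted p = 0.00104, 7.41e-05, 9.98e-07 and 1.17e-05), and none with an estimated correlation (adjusted p = 0.289, 0.222, 0.136 and 0.181). On Ace 1 fell and on Sor and Lac 0 were called (camera, adjusted p = 0.930, 0.789 and 0.439), with medians on Ace and Sor that turned sign with upper-quartile scaling. The Ace median was 0.01 and its mean -0.01. Of 10 terminal oxidase genes all rose on Ace and 8 on Suc, cydB, of cytochrome bd, to 575 ± 13.4 from 208 ± 21.7 CPM on Ace (camera, adjusted p = 0.000459 and 0.000828, and adjusted p = 0.247 and 0.262 with an estimated correlation). On Sor 5 rose, on Gly 3, and on G6P 2 rose and 1 fell, or 3 and 2 adjusted over the list alone (adjusted p = 0.114, 0.193 and 0.374). In CY104 5 rose and 5 fell, with a median of -0.08 and a mean of 0.46 (camera, adjusted p = 0.930), cbdA, of a second cytochrome bd, at 66.6 ± 2.84 from 6.97 ± 1.08 CPM. On Lac 0 were called, with a median of -0.01 that turned sign with RLE scaling (camera, adjusted p = 0.736).

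Iron uptake genes depended on the libraries with high zinc-uptake transcripts. Of 31, 19 fell and 1 rose on Ace, 23 fell on Gly, or 25 adjusted over the list alone, 24 fell on Suc and 13 on G6P, or 16 adjusted over the list alone. Without the 3 zinc libraries, 13 fell and 3 rose on Ace, 18 fell and 1 rose on Gly, 22 fell and 1 rose on Suc, and 10 fell and 3 rose on G6P. Camera gave adjusted p = 0.00846, 4.57e-05, 1.95e-05 and 0.00138, none kept with an estimated correlation (adjusted p = 0.638, 0.451, 0.427 and 0.558). fiu, a catecholate siderophore receptor, went from 564 ± 313 CPM on Glc to 116.5 ± 15.03 on Ace (log2 -2.27 ± 0.35; edgeR, adjusted p = 1.74e-05, n = 3), and by -1.73 without the 3 libraries. On Sor 2 rose and 5 fell, or 2 and 1 adjusted over the list alone, and 19 rose and 2 fell without them (camera, adjusted p = 0.930). In CY104 7 rose and 15 fell, or 8 rose adjusted over the list alone, and 11 and 14 without them, where the median went from -0.16 to 0.07 (camera, adjusted p = 0.442). On Lac 1 fell, and 16 fell in the fit of the 6 Glc and Lac libraries with a replicate block (median -0.28; camera, adjusted p = 7.82e-09, and adjusted p = 0.284 with an estimated correlation).

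Smaller lists moved less evenly. The 3 glycine cleavage genes fell on Ace and Sor and in CY104, gcvT to 100.5 ± 1.40 from 231 ± 13.5 CPM in the last (camera, adjusted p = 0.0351, 0.0214 and 0.0113, and adjusted p = 0.262, 0.239 and 0.198 with an estimated correlation). On Suc all 3 rose, on Gly 2 fell, on G6P gcvH rose, or all 3 adjusted over the list alone, and on Lac gcvH rose (camera, adjusted p = 0.192, 0.288, 0.0639 and 0.00729, and for Lac adjusted p = 0.173 with an estimated correlation). Of 11 pentose phosphate and Entner-Doudoroff genes 7 rose and 2 fell in CY104, talA, transaldolase, to 481 ± 30.1 from 58.1 ± 6.03 CPM (median 0.34; camera, adjusted p = 0.0214, and adjusted p = 0.222 with an estimated correlation). The list was called on no source (camera, adjusted p from 0.0656 on Lac to 0.924 on Ace), where 5 rose and 4 fell on Ace, 4 and 3 on G6P, 4 and 3 on Gly, 1 and 1 on Lac, 3 and 7 on Sor and 6 and 2 on Suc. Adjusted over the list alone these were 5 and 5, 5 and 3, 5 and 3, 4 and 2, 3 and 7, and 7 and 3. Its median on Suc was 0.13 and its mean -0.04. The 5 curli genes tested, of 6 counted, rose in CY104, csgD, their activator, to 17.8 ± 1.76 from 3.12 ± 0.953 CPM (median 2.50; camera, adjusted p = 0.0443, and adjusted p = 0.112 with an estimated correlation). Without the 3 zinc libraries 6 were tested and 5 rose (median 2.04). On the sources at most 2 rose and the list was not called (camera, adjusted p from 0.469 on Sor to 0.924 on Suc). The glucose 6-phosphate uptake list was called in no comparison (camera, adjusted p from 0.0530 on G6P to 0.941 on Gly), and uhpT rose by log2 1.80 on Ace, 1.66 on Gly and 1.63 on Sor and fell by 0.89 in CY104.

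Some small counts of list members also moved when the 3 zinc libraries were left out, a setting chosen after seeing the data. On G6P these were acid resistance, from 5 to 3 falling, pentose phosphate and Entner-Doudoroff genes, from 3 to 1 falling, NADH dehydrogenase I, from 1 to 3 falling, terminal oxidases, from 2 to 0 rising, glycine cleavage, from 1 to 2 rising, glycolysis, from 2 to 1 falling, and heat shock and the tricarboxylic acid cycle, each from 0 to 1 rising. On Lac they were iron uptake, from 1 to 3 falling, fatty acid degradation and amino acid biosynthesis, each from 1 to 2 falling, and pentose phosphate and Entner-Doudoroff genes, from 1 rising and 1 falling to 0 of each. On Suc curli genes went from 2 rising to 1 rising and 1 falling, glycolysis from 1 to 2 rising, other sugars from 2 to 1 falling, and glucose 6-phosphate uptake from 1 rising and 2 falling to 2 rising and 1 falling. On Gly glucose 6-phosphate uptake went from 2 to 1 falling, and on Sor other sugars went from 1 to 0 falling and heat shock from 0 to 1 rising.

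The effect of the CY104 genotype was compared with that of each source across the 4419 genes, which are not independent replicates. Pearson's r between the log2 fold changes, both against Glc, was 0.241 for Ace, 0.207 for Sor, 0.144 for G6P, 0.14 for Gly, 0.0694 for Suc and -0.0705 for Lac, and Spearman's rho was 0.396, 0.411, -0.0420, 0.308, 0.194 and -0.116. Because both effects share the Glc libraries, 20 simulations of unchanged groups gave mean r of 0.519, 0.537, 0.521, 0.526, 0.529 and 0.519 in that order. Every fold change in them is noise, so r of this size follows from the shared libraries by construction. Real changes widen the spread of the fold changes, so the observed r cannot be set against these values, and covariances were compared. The observed covariance was 0.341, 0.311, 0.0933, 0.171, 0.0795 and -0.0342, against simulated covariances of 0.0245 to 0.0254. With each source set against the mean of the other 5 sources, so that no library was shared and the values are relative to the other sources, r was 0.214 for Ace, 0.181 for Sor, 0.0173 for Gly, -0.0626 for G6P, -0.154 for Suc and -0.229 for Lac, and rho was 0.338, 0.372, 0.0942, -0.285, -0.187 and -0.361. Genes lower in CY104 and on Ace numbered 836 where independent lists give 443.5, and genes higher in both numbered 701 against 455. For Sor these were 848 against 451 and 744 against 484, for Gly 655 against 353 and 558 against 399, and for Suc 572 against 354 and 500 against 391. On G6P 261 were lower in both against 199 and 85 higher in both against 155, while 296 genes lower in CY104 were higher on G6P against 151. For Lac 36 genes lower in CY104 were higher against 16.7 and 29 higher in CY104 were lower against 12.7. The 3 Glc libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls.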

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

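Most results kept their direction and their side of the threshold. The numbers of genes called stayed within 1.5 times their values under RLE and upper-quartile scaling, without a filter, with a mean of at least 50 counts and with DESeq2, which called 2823 genes on Ace and 121 on Lac. Requiring a log2 fold change of at least 1 as well left 823 genes on Ace, 133 on G6P, 592 on Gly, 16 on Lac, 938 on Sor, 570 on Suc and 884 in CY104, by its construction. At a log2 fold change of at least 2 the specific genes numbered 24 for Ace, 11 for G6P, 19 for Sor and 1 for Suc. With an estimated correlation camera called 60 pairs of list and comparison. Lac was the least stable comparison: a fit of only the 6 libraries called 34 genes and the same fit with a replicate block called 140, and the cause was not tested. With the replicate block in the fit of 24 libraries the counts were 2788 on Ace, 1095 on G6P, 2336 on Gly, 93 on Lac, 2916 on Sor, 2316 on Suc, 2819 in CY104 and 3597 for the F test, and the block changed no other call of a list. Of 24 libraries, 10 deviated most like a library of their own number. The correlation of the CY104 effect with a source was -0.0626 for G6P, -0.154 for Suc, 0.0173 for Gly and -0.229 for Lac when the source was set against the other 5 sources, a setting that centres the sources on each other, so that some of these values must be negative. It was 0.287 for Ace and 0.246 for Sor without crp, cyaA and the blocks of 0 counts, an alternative chosen after seeing the data, and the cause was not tested.

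Leaving out each library in turn gave 2646 to 2709 genes on Ace, 862 to 1016 on G6P, 2166 to 2238 on Gly, 79 to 107 on Lac, 2772 to 2852 on Sor, 2136 to 2206 on Suc, 2665 to 2761 in CY104 and 3556 to 3630 in the F test. Specific genes ran from 49 to 54 for Ace, 59 to 70 for G6P, 0 to 0 for Glc, 11 to 12 for Gly, 8 to 8 for Lac, 34 to 39 for Sor and 3 to 4 for Suc. The correlations ran from 0.225 to 0.265 for Ace, 0.128 to 0.188 for G6P, 0.116 to 0.175 for Gly, -0.0779 to 0.00825 for Lac, 0.190 to 0.234 for Sor and 0.0426 to 0.109 for Suc, and the list calls from 123 to 129. Of 900 results on named genes, 63 lost their call in at least 1 of these fits. The other 837 include genes not called in the main fit, and only the fit with the largest adjusted p was judged. With only the 6 libraries compared, 56 lost their call and 1 gained one. No alternative for ribosomal RNA was run, since no such features were counted, and none for a pseudocount or a filter of low normalized values, since counts were tested. A gene at 0 counts in a library can still reach 0.154 to 0.225 CPM at these depths.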

Other observations

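The groups in this paragraph were chosen after their values were seen. Colanic acid synthesis genes, which build the capsule polysaccharide, were near 0 on Glc and rose in CY104 in all 10 genes tested (median log2 fold change 8.07, range 6.75 to 9.30). rcsA, an activator of capsule genes, rose to 584 ± 74.5 CPM from 5.42 ± 1.49 (edgeR, adjusted p = 3.11e-16, n = 3). On Gly 3 rose and 1 fell (median 0.51), on Sor 3 rose (median 0.96, range 0.25 to 2.23), on Suc 3 rose (median -0.04), and 0 were called by edgeR on Ace, G6P and Lac. Plasmid genes took 3.84 ± 0.175% of counts on Sor, 3.27 ± 0.104% on Ace, 2.94 ± 0.217% on Suc and 2.81 ± 0.0834% on Gly, against 2.02 ± 0.0492% on Glc. Of 75 tested, 57 rose on Sor and on Ace, 51 on Gly and 49 on Suc, where 1 fell, while in CY104, where the share was 2.07 ± 0.249%, 38 fell and 4 rose after TMM scaling with factors of 1.20 to 1.25. Against Ace in place of Glc, flagellar genes rose in 51 of 51 on Gly, 49 on Sor and 51 on Suc (camera, unadjusted p = 3.84e-39, 5.85e-39 and 1.60e-36, and unadjusted p = 0.000414, 0.000423 and 0.000578 with an estimated correlation). Of 86 noncoding RNA genes tested, 34 fell and 6 rose on Suc, and 18 rose and 20 fell on Ace.

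For the patterns that follow, the tests of a label swap, of a batch of libraries numbered 3 and of lost reads were chosen only after the result was seen. The bounds for the tests by other splits and with the source set against the other sources, a fit planned before, were also written after. Zinc-uptake transcripts were high in library 3 of Glc and Lac. A swap of the 2 labels was excluded, since lacZ was 528-fold higher in Lac library 3 than in Glc library 3. zinT exceeded both other libraries by over 2-fold in library 3 of only 3 of 8 groups. This excludes only a batch that raises zinT over 2-fold in every library numbered 3. By smaller margins zinT was also highest in library 3 on Ace (6.81 CPM against 3.86 and 3.65), Gly and Suc, but not on Sor or in CY104. A weaker batch of libraries numbered 3 therefore stays open, as does a batch of those 3 libraries. The iron uptake list differed by a median of 0.484 in Glc and 0.553 in Lac, so a general change of metal uptake could neither be kept nor dropped. No biological explanation was tested.

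Neighbouring genes were at 0 counts in 1 strain. Block A, ravA to rbsR_N at chromosome 505938 to 515068, held 8 features at 0 in 21 wild-type libraries, and block B, intZ to yffS at 3799538 to 3806012, held 9 at 0 in the 3 CY104 libraries. Only 0.0216% of features outside the blocks, the 1 feature cyaA, were at 0 in 1 strain and above 100 in the other. The blocks were picked for such counts and then left out, so this share cannot decide on low expression. In block A all 8 features were at 0 counts in each of the 21 wild-type libraries, against 231 to 5488 counts over the 3 CY104 libraries. This argues against a low but measurable level of these 8 features in the wild type. Counts cannot tell full silence from a DNA difference, and for block B low expression stays open. Reads lost from both strains in alignment or counting were excluded by a median of 1415 counts of a block feature in the other strain, counts the blocks were picked for, while a loss from 1 strain alone stays open. A DNA difference between the strains with its ends at the blocks stays open, because only 3 of 4 neighbouring features had over 100 counts in both strains: viaA had 77 in the wild type and 3776 in CY104, and insH1 after block A has near-identical copies.

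The CY104 effect correlated with the Ace and Sor effects. With the source set against the other 5 sources the smaller of the 2 correlations was 0.181. These correlations are relative, since each source is centred on the others. Ace and Sor had the largest covariances against Glc, so a positive sign was fixed in advance. Those covariances, 0.341 and 0.311, lay above the 0.0245 and 0.0253 of simulated unchanged groups. Within the spread between libraries, this argues against the shared Glc libraries as the whole cause. Without the ribosomal, translation, stress and acid resistance lists at least 87.8% of the correlation was kept, at 0.212 for Ace and 0.185 for Sor over 4293 genes, so the members of these lists alone do not carry it. Most genes stayed in, so other genes that move with these members were not tested as a cause. Which regulators the strain and the sources share was not tested.

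The libraries were also split in other ways. Of the 10 splits of 6 libraries into 3 and 3, only 1, the real one, reached the real count in each comparison, and with 10 splits this share cannot get below 0.05. The real count and the highest other were 2805 and 0 on Ace, 1109 and 0 on G6P, 2345 and 0 on Gly, 92 and 70 on Lac, 2918 and 0 on Sor, 2325 and 0 on Suc and 2832 and 1 in CY104. For Lac the other splits that parted all 3 numbered pairs called 0, 1 and 0 genes. Splits that parted only 1 pair also called 0 when library 3 of Glc and of Lac lay on opposite sides. With both on the same side the splits called 8, 19, 39 and 70 genes. The counts thus followed the placing of these 2 libraries and do not speak for pairing by number. Among 100 splits of the 21 wild-type libraries, 1 reached the 3623 genes of the F test, the next highest being 2139. For specific genes 1 of 100 reached the counts of 52 for Ace, 64 for G6P, 12 for Gly, 8 for Lac, 38 for Sor and 3 for Suc, with 0 as the highest other, and for Glc 100 of 100 reached its count of 0. Such splits mix sources within a group, which widens the spread, so counts of 0 specific genes were nearly certain. Pairwise splits mix unlike groups in the same way, so neither of these results argues against chance.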
